A study of Mus musculus with 6 samples.

How the data were processed

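Poly(A) RNA of 6 mouse liver samples, 3 of the R159 group and 3 of the vehicle group, all on a high-fat diet, was made into stranded libraries with a kit that primes with random and oligo(dT) primers, and sequenced as paired-end reads of 50 bp, per the labels' protocols. The submitters' processing notes list FastQC 0.11.9, cutadapt, STAR 2.7.8a, DESeq2 (given as 3.5), R 4.2.3 and the build mm39, with no role or order. The counter, the annotation and any gene filter are not given in the sources used here, nor whether counting used strand, so reads of overlapping and antisense genes cannot be told apart with certainty.

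The deposited tables, 1 per sample, hold 18720 rows with a gene symbol and a value (18705 distinct symbols, 14 of them listed more than once). The unit of the deposited values is a signal: estimated, fractional gene counts divided by 1 factor per sample. The median log ratio to the geometric mean was the same to 4 decimals in all 6 samples. Low values clustered at multiples of 1 step per library, which gives the value of 1 estimated read and the depth (51.29, 51.26 and 55.74 M reads in R159 replicates 1 to 3, and 65.96, 76.69 and 70.56 M reads in vehicle). Only 66.8% to 73.6% of values under 200 reads were whole within 0.02 reads, so no count model was used. At such depth, counting noise is small for all but the lowest genes, and the spread between libraries sets the precision.

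Genes with a mean value of at least 10 over the 6 samples were kept (16594; 2126 fell under the filter). Values were analysed as log2(value + 1) with limma 3.58.1 in R 4.3.3 (eBayes with trend, group as the only term), with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. Gene lists, 43 in number, covering pathways of the liver, cell types that a piece of liver could hold and technical groups, were tested with camera (preset correlation 0.01) where at least 5 members were measured, which left 42, and also with an estimated correlation and with fry. The design, the lists, the other settings to try and the rule for named genes were fixed before the data were examined.

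The rule named, among called genes whose groups do not overlap, the 10 largest changes in each direction (leaving out unnamed models, pseudogenes and immune receptor segments), the 4 members of smallest p in each called list, the 2 of smallest p in the acute phase, gp130, cytokine, fibrosis, lipogenesis, lipid droplet, cholesterol and PPARalpha lists, and 18 genes always: Il6st, Il6ra, Stat3, Socs3, Src, Yes1, Yap1, Saa1, Lcn2, Tnf, Il1b, Ccl2, Adgre1, Col1a1, Pparg, Cd36, Scd1 and Cyp7a1. It gave 118 genes, of which the text gives a part; some results under this rule are not reported here.

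A reference annotation of another mouse build than mm39 was used only for transcript length (the longest coding transcript), GC content and overlaps between genes, and no coordinates are given. It gave a length for 15844 of the tested genes (95.5%). The length trend was measured over coding genes with a mean value of at least 100, and removed, as an alternative chosen after seeing the data, by subtracting from each library a lowess curve (span 0.3) of its deviations on log2 length. Random lists, 10000 per list, were matched on length and expression. Other alternatives were another normalization, pseudocounts of 0.5 and 8, no filter or a mean of 50, other empirical Bayes settings, sample weights, a replicate block, leaving out each library, a threshold of 0.1, a minimum log2 change of 1, and rescaling without the 20 highest genes. limma-voom on estimated reads and coding genes alone were added after seeing the data.

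The method was tested on simulated data for R159 against vehicle with 16594 genes, 200 of them changed. Of genes changed by 2 on the log2 scale 65% were called, and of those changed by 1, 22%. Unchanged genes made up 9.38% of the calls, above the nominal 5%, and limma called 0 genes when no change was put in (874 at an unadjusted p under 0.05). Both lists that were shifted by 1 were called in the right direction, and removing a planted length trend brought its rho from -0.72 to 0.0068. The planted trend had the form that the correction removes. It therefore checked the code only, and not whether true changes of short or long transcripts are kept. Simulated genes were drawn independently of one another, so camera's preset correlation was not put to a test. Each gene had the same spread in both groups, and the run with no change had no length trend. The real R159 libraries were less alike than the vehicle ones (median r 0.943 against 0.981). The 0 calls thus do not bound the false calls in the real data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.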

Results

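Poly(A) RNA was sequenced from the livers of aged male C57BL/6 mice kept on a high-fat diet. The mice were 1 year old and received intraperitoneal injections of R159, a compound known here only by its code name, or of vehicle. Injections were given 2 times a week for 12 weeks. There were 3 R159 libraries and 3 vehicle libraries, and the labels do not say outright that each came from a separate animal, so p-values measure the spread between these samples, which may in part be technical. The series title places the compound on a non-canonical branch of signalling from gp130, the shared receptor subunit of the interleukin-6 cytokine family, and the comparison asks which liver transcripts differ between drug and vehicle. Estimated depth was 51.29, 51.26 and 55.74 M reads in R159 replicates 1 to 3, and 65.96, 76.69 and 70.56 M reads in vehicle replicates 1 to 3, so the R159 libraries were the shallower ones. Values below are normalised estimated counts, given as mean ± SD with n = 3 per group, and log2 fold changes (R159 minus vehicle) are on the log2(value + 1) scale with their SE and limma's Benjamini-Hochberg adjusted p.

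R159 livers held less mRNA for the gp130 receptor subunit, and 18 of 34 interferon-stimulated genes, 9 of 24 antioxidant genes controlled by NRF2, 11 of 32 fibrosis genes and 8 of 23 lipid droplet genes were called lower. Called higher were 10 of 26 male-biased genes, many of them major urinary protein genes, 6 of 9 erythroid genes, 33 of 39 ribosomal protein genes and 21 of 37 respiratory chain genes. As lists, each of these was called by camera with a preset correlation, and each had adjusted p = 0.635 with an estimated correlation. The ribosomal and respiratory chain transcripts are short (median 946 and 1186 nt), and short transcripts were higher in R159 in general. The fibrosis transcripts are long (median 4697 nt), and of coding genes of 4312 to 5142 nt 33.5% were called lower. The fibrosis count is thus near the share at that length, and after length correction 3 of these genes were lower and 1 higher. limma called 4479 of 16594 tested genes (27%), 2125 higher and 2354 lower in R159. Among all tested genes, 7659 (46.2%) had groups that did not overlap, where chance gives 10%. Calls also followed transcript length and coding status: of the called genes without a protein-coding record in the reference, 678 were higher and 108 lower, and among coding genes 1447 were higher and 2246 lower. The count of called genes dropped to 2498 without vehicle replicate 1, to 1854 without vehicle replicate 2 and to 2185 without vehicle replicate 3. With the transcript length trend removed, an alternative chosen after seeing the data, 2863 genes were called.

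Across 11022 protein-coding genes the log2 fold change was correlated with transcript length (Spearman's rho = -0.498 across genes, which are not independent replicates), and with GC content hardly at all (rho = 0.0732). In the decile of shortest transcripts, 204 to 1295 nt, the median log2 fold change was 0.70 and 48.3% of genes were called higher. In the decile of longest transcripts the median was -0.53 and 37.1% were called lower. The correlation of a library's deviation from the 6-library mean with transcript length was 0.018, -0.60 and -0.49 in R159 replicates 1 to 3, and 0.34, 0.47 and 0.50 in the vehicle replicates. R159 replicate 2 stood farthest from the vehicle libraries (Pearson's r across genes 0.910 to 0.918), with 973 genes listed at 0. Vehicle libraries correlated with one another at 0.979 to 0.986 and R159 libraries at 0.939 to 0.949. R159 replicates 1 and 3 correlated with the vehicle libraries at 0.937 to 0.942 and 0.937 to 0.939, nearly as well as with their own group. The share of values from mitochondrially encoded genes was 10.6%, 13.6% and 8.42% in R159 and 7.43%, 5.01% and 5.29% in vehicle.

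**Figure D1:**
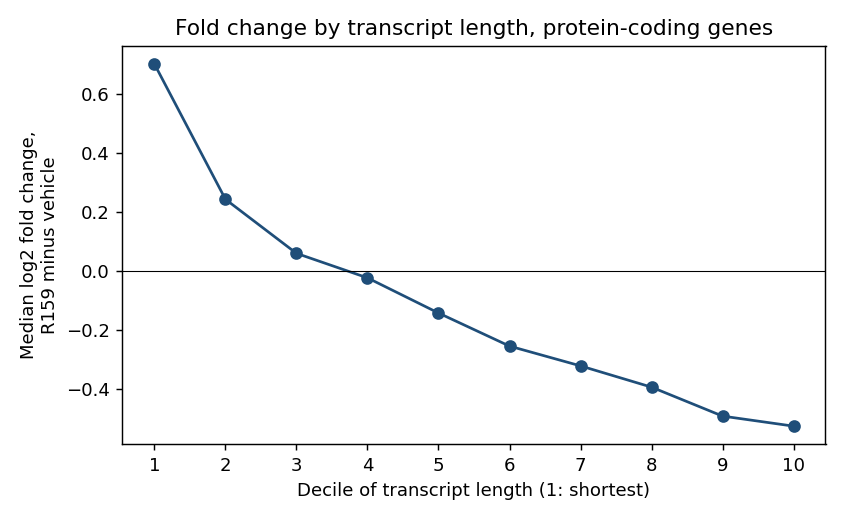
Median log2 fold change (R159 minus vehicle, y axis) of protein-coding genes in 10 deciles of transcript length (x axis, shortest at the left); each point is 1 decile. The median goes from 0.70 in the shortest decile to -0.53 in the longest.

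Il6st, which encodes gp130, fell from 8022 ± 799 in vehicle to 3687 ± 699.7 in R159 (log2 fold change -1.14, SE 0.18, limma adjusted p = 0.00486). It stayed past the threshold after removal of the length trend (-0.62, adjusted p = 0.0194); its transcript of 8678 nt is among the long ones. Stat3, the transcription factor activated through gp130, was also lower (-0.97, adjusted p = 0.0199), but was not past the threshold without vehicle replicate 2 (-0.90, adjusted p = 0.0735), without vehicle replicate 3 (-0.97, adjusted p = 0.0609), without the empirical Bayes trend (-0.97, adjusted p = 0.062) or after length correction (-0.49, adjusted p = 0.0857). Ptpn11, which encodes the phosphatase SHP2, and Cish, a STAT-induced inhibitor of cytokine signalling, were lower by log2 fold changes of -1.42 and -1.73 (limma adjusted p = 0.00343 and 0.00299). Socs3, the feedback inhibitor induced by STAT3, was 595 ± 165 in R159 and 572 ± 152 in vehicle (adjusted p = 0.909), and Il6ra gave a log2 fold change of -0.59 (adjusted p = 0.201). Of 25 measured members of the gp130 and STAT3 list, 3 were higher and 6 lower, the same numbers when adjusted over the list alone, and the list was not called by camera (adjusted p = 0.216). fry, which asks whether the members of a list move on balance one way and compares it with no other genes, called it (adjusted p = 0.0398, lower).

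Src, a tyrosine kinase that binds many receptors, fell from 262 ± 91.7 to 105 ± 13.5 (-1.27, SE 0.30, limma adjusted p = 0.0158), and lost its call without vehicle replicate 1 (adjusted p = 0.0676) and after length correction (-0.99, adjusted p = 0.0531). Its relative Yes1 gave -0.40 (adjusted p = 0.0966). Of 12 Src family members and regulators, 3 were lower and 0 higher (3 and 0 adjusted over the list alone; camera adjusted p = 0.103, fry adjusted p = 0.0422, lower). Among 22 YAP and TEAD targets, 9 were lower and 0 higher (9 adjusted over the list alone; camera adjusted p = 0.00177, and adjusted p = 0.635 with an estimated correlation). Crim1, Axl, Lats2 and the coactivator gene Yap1 (-0.86, SE 0.15, limma adjusted p = 0.0065) were among them. Their median transcript length was 4512 nt, and after length correction the list was no longer called (camera adjusted p = 0.0556). Of 17 ERK immediate targets, 5 were lower, among them Ccnd1 and Dusp4, and 1, Spred3, was higher (the same numbers adjusted over the list alone; camera adjusted p = 0.0339, adjusted p = 0.635 with an estimated correlation, and 0.116 after length correction).

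**Figure D2:**
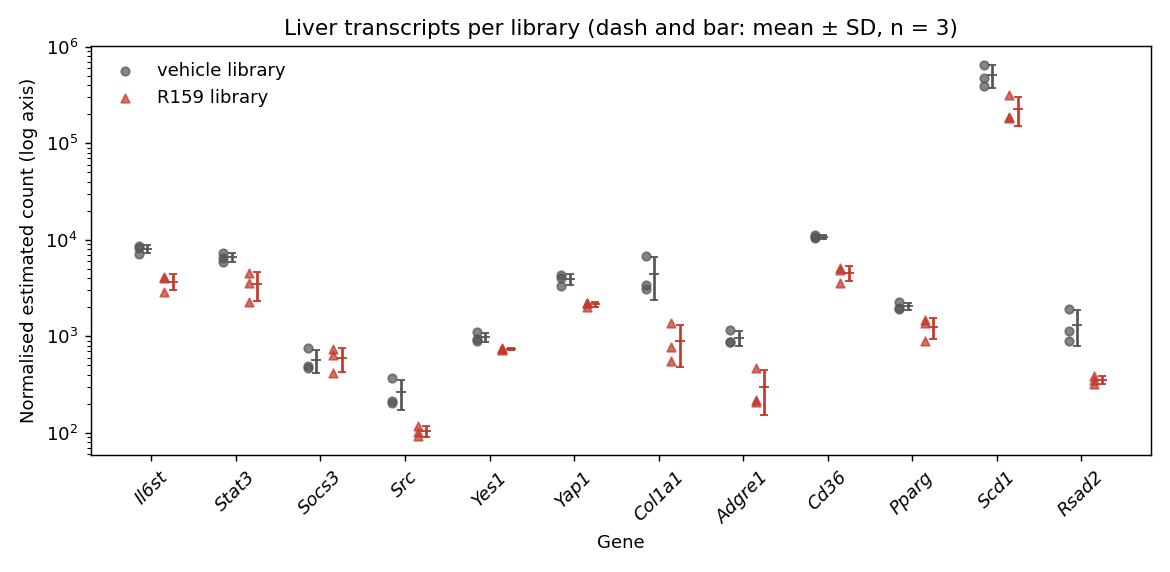
Normalised estimated counts (y axis, log scale) of 12 genes (x axis) in each library; circles are vehicle, triangles are R159, and dashes with bars are mean ± SD, n = 3. Il6st lies at 3687 in R159 against 8022 in vehicle on average, while Socs3 lies at 595 against 572.

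Among inflammatory lists, camera called the interferon-stimulated list and not the cytokine or acute phase list, but differences between lists were not tested. The cytokine and acute phase medians lay below 0 as well (-0.413 and -0.143). Of 34 interferon-stimulated genes, 18 fell and 1 rose (22 and 1 adjusted over the list alone), with a median log2 fold change of -0.97 (camera adjusted p = 0.000243, and adjusted p = 0.635 with an estimated correlation). Rsad2, an antiviral enzyme, fell from 1317 ± 532 to 356 ± 34.6 (-1.81, SE 0.27, limma adjusted p = 0.00416), and Ifi44, Oasl1 and Ifih1 fell too, with log2 fold changes of -2.07, -1.39 and -0.89. The median length of the interferon-stimulated transcripts was 2556 nt and their median after length correction was -1.003, with 18 members lower. Ifih1 was then not called (-0.449, limma adjusted p = 0.0963), while Rsad2, Ifi44 and Oasl1 were. Of 32 cytokine, chemokine and NF-kB target genes, 3 were higher and 5 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.354). Il18 was higher and Tnfaip3 lower, while limma did not call Tnf (adjusted p = 0.784), Il1b (0.0805) or Ccl2 (0.393). After length correction Il18 was not called (0.426, limma adjusted p = 0.155), while Tnfaip3 was (-1.144, adjusted p = 0.0244). Of 30 acute phase genes, 4 were higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.718). Saa3 rose by 1.56 and Steap4 fell by 0.98 on the log2 scale (limma adjusted p = 0.00799 and 0.00717). Saa1 varied widely among R159 libraries (35995 ± 36200 against 10411 ± 4430.0, adjusted p = 0.272), and Lcn2 gave -0.63 (adjusted p = 0.362).

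Markers of other liver cell types moved apart. Of 20 markers of monocyte-derived and lipid-associated macrophages, 5 were lower and 1 higher (6 and 1 adjusted over the list alone; camera adjusted p = 0.0384, adjusted p = 0.635 with an estimated correlation). Gpnmb fell from 931 ± 379 to 115 ± 49.9 (-3.03, SE 0.43, limma adjusted p = 0.00382). Kupffer cell markers, 1 higher and 4 lower of 18, were not called (camera adjusted p = 0.611), though Adgre1, which encodes F4/80, fell by 1.77 on the log2 scale (SE 0.31, limma adjusted p = 0.00595). Of 12 MHC class II presentation genes limma called 0 (0 adjusted over the list alone, 8 at an unadjusted p under 0.05), with camera adjusted p = 0.151. After length correction 6 were lower (camera adjusted p = 0.00603, and adjusted p = 0.744 with an estimated correlation). Of 20 T and NK cell markers limma called 0 (0 adjusted over the list alone, 1 at an unadjusted p under 0.05; camera adjusted p = 0.924). Of 20 B and plasma cell markers, 3 were higher, Jchain, Igkc and Iglc2, and 1 lower, Derl3 (2 and 1 adjusted over the list alone; camera adjusted p = 0.0336, adjusted p = 0.635 with an estimated correlation, and 0.168 after length correction). Sinusoidal endothelial markers had 1 higher and 1 lower of 20 (camera adjusted p = 0.294). Of 16 cholangiocyte markers, 4 were lower, among them Cdh1 and Krt8, and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.00909, adjusted p = 0.635 with an estimated correlation).

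Of 32 stellate cell and fibrosis genes, 11 fell and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p = 0.000897, and adjusted p = 0.635 with an estimated correlation). Col1a1, the main fibrillar collagen of scar tissue, fell from 4466 ± 2087 to 895 ± 417 (-2.32, SE 0.37, limma adjusted p = 0.00483), and Col1a2 fell by 2.30 on the log2 scale. These transcripts were long, 4697 nt at the median; after length correction 3 were lower and 1 higher, the list median was -0.49, and Col1a1 remained past the threshold (-1.85, adjusted p = 0.0206) while Col4a1 (adjusted p = 0.0913) and Col4a2 (0.0583) did not.

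Of 23 lipid droplet and PPARgamma targets, 8 fell and 2 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.0336, and adjusted p = 0.635 with an estimated correlation). Cd36, a fatty acid transporter, fell from 10779 ± 489 to 4525 ± 821 (-1.27, SE 0.17, limma adjusted p = 0.0036), and Fitm2 (-1.33) and Pparg (-0.75) fell as well. Cd36 and Pparg kept their calls after length correction (limma adjusted p = 0.00594 and 0.0164). Of 35 PPARalpha targets and fatty acid oxidation genes, 7 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.00298, adjusted p = 0.635 with an estimated correlation); Ppara itself fell from 5764 ± 817 to 1532 ± 675. The lipogenic list had 1 gene higher and 4 lower of 23 (1 and 3 adjusted over the list alone; camera adjusted p = 0.365). In it Mlxipl, which encodes the carbohydrate-responsive factor ChREBP, rose by 1.46 and Acaca fell by 0.97 on the log2 scale. After length correction Mlxipl kept its call (1.715, limma adjusted p = 0.00466) and Acaca did not (-0.468, adjusted p = 0.0806). Scd1, the stearoyl-CoA desaturase, lay just past the threshold (-1.18, SE 0.38, limma adjusted p = 0.049; 0.146 after length correction). The list of 26 cholesterol synthesis genes was not called (camera adjusted p = 0.249), and in it Tm7sf2 was higher (log2 fold change 1.28, SE 0.38, limma adjusted p = 0.0357). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, gave 0.32 (adjusted p = 0.654).

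Of 24 NRF2 targets, 9 fell and 0 rose (13 and 0 adjusted over the list alone; camera adjusted p = 0.000486, and adjusted p = 0.635 with an estimated correlation). Pgd and Txnrd1, enzymes of NADPH and thioredoxin metabolism, had log2 fold changes of -0.88 and -1.03, and after length correction 12 members were lower with a median of -0.80. Slc7a11, the cystine transporter, was at most 1 estimated read in every R159 library and 62.1 ± 49.4 in vehicle. Of 33 CAR and PXR target genes, 3 rose and 7 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.0336, adjusted p = 0.635 with an estimated correlation), with Cyp3a11 at 30231 ± 6911 against 94007 ± 23500 and Sult1d1 higher. Of 29 unfolded protein and integrated stress response genes, 5 were lower, among them Canx and Sel1l, and 1 higher (5 and 1 adjusted over the list alone; camera adjusted p = 0.0394, adjusted p = 0.635 with an estimated correlation). Of 30 cell cycle genes, 6 were lower and 0 higher (4 adjusted over the list alone; camera adjusted p = 0.00276, adjusted p = 0.635 with an estimated correlation), among them the replication helicase genes Mcm2, Mcm4 and Mcm5.

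The groups that rose were mainly short transcripts. Of 39 cytosolic ribosomal protein genes, 33 rose and 0 fell (33 adjusted over the list alone), with a median length of 946 nt (camera adjusted p = 7.23e-11, and adjusted p = 0.635 with an estimated correlation); after length correction 10 were higher and 1 lower (camera adjusted p = 0.0359, and adjusted p = 0.744 with an estimated correlation). Of 37 nuclear-encoded respiratory chain genes, 21 rose and 1 fell (25 and 3 adjusted over the list alone; median length 1186 nt; camera adjusted p = 2e-05, adjusted p = 0.635 with an estimated correlation, and 0.209 after length correction). Of 13 mitochondrially encoded transcripts, 5 rose (11 adjusted over the list alone; median length 784 nt; camera adjusted p = 0.000236, adjusted p = 0.635 with an estimated correlation, and 0.337 after length correction). Of 26 male-biased growth hormone and STAT5 targets, 10 rose and 0 fell (10 adjusted over the list alone; median length 1694 nt; camera adjusted p = 0.000486, adjusted p = 0.635 with an estimated correlation). Mup3, a major urinary protein gene, rose from 120520 ± 28630 to 498050 ± 121500 (2.05, SE 0.34, limma adjusted p = 0.00494), and 9 members were higher after length correction (camera adjusted p = 0.00178, and adjusted p = 0.744 with an estimated correlation). Mup genes are near-identical copies whose reads may be divided uncertainly. Female-biased genes had 3 lower, among them Cyp2a4, and 1 higher, Cyp17a1, of 20 (3 and 1 adjusted over the list alone; camera adjusted p = 0.0497, adjusted p = 0.635 with an estimated correlation, and 0.0872 after length correction). Of 9 erythroid markers, 6 rose and 0 fell (6 adjusted over the list alone; median length 1280 nt; camera adjusted p = 0.000897, and adjusted p = 0.635 with an estimated correlation). Hbb-bt, a beta-globin gene, rose from 672 ± 247 to 4129 ± 953 (2.65, SE 0.27, limma adjusted p = 0.00299; 1.69 and 0.0115 after length correction). After length correction the erythroid list stayed called with a median of 1.29 (camera adjusted p = 0.0099, and adjusted p = 0.658 with an estimated correlation) and 2 of its members were called. Hbb-bs (1.29, adjusted p = 0.0773), Hba-a1 (1.23, adjusted p = 0.0623) and Hba-a2 (0.71, adjusted p = 0.237) were not.

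**Figure D3:**
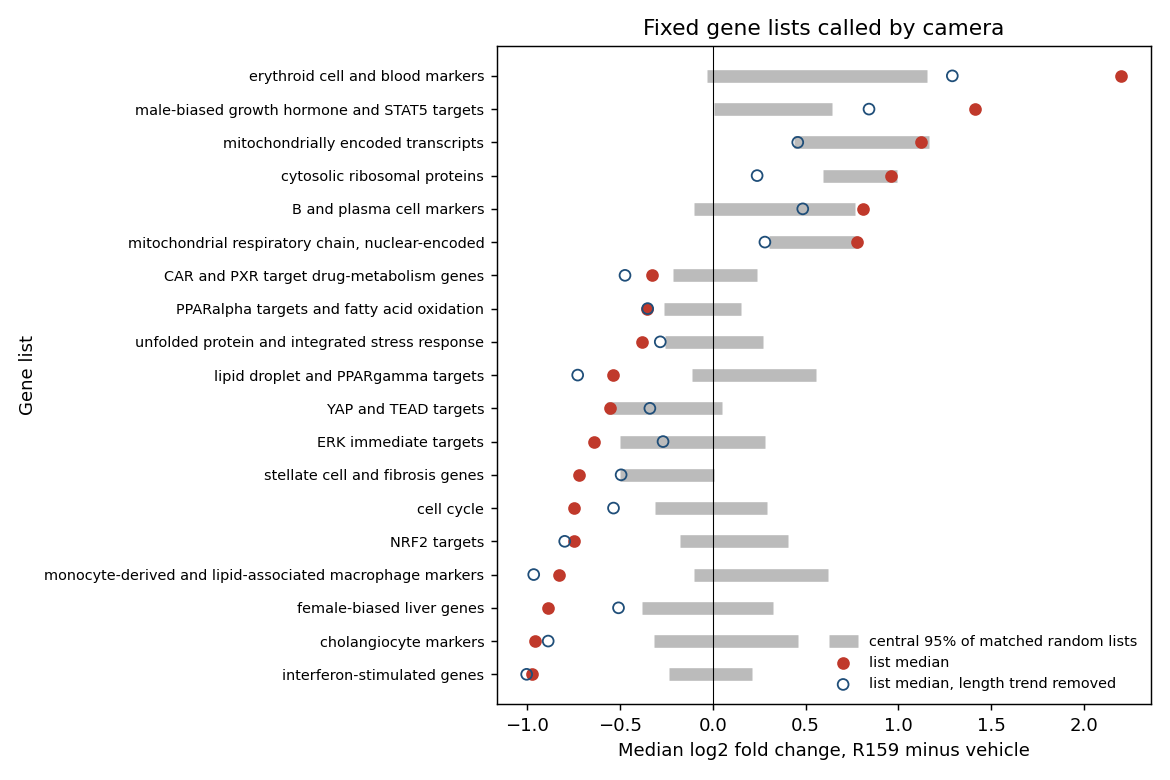
Median log2 fold change (x axis, R159 minus vehicle) of the 19 called gene lists (y axis). Filled points are list medians over members with a known length, open points the medians with the length trend removed, and grey bars the central 95% of random lists matched on length and expression. The ribosomal protein median, 0.959, lies inside its bar (0.594 to 0.995), and the interferon-stimulated median, -0.972, lies below its bar (-0.238 to 0.21).

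In all, camera called 19 of 42 lists, 6 higher and 13 lower. With an estimated correlation 0 were called (2 at an unadjusted p under 0.05, lowest adjusted p 0.635). fry called 5. Of these, 3 (YAP and TEAD, CAR and PXR, and erythroid) were among the 19 and 2 (gp130 and STAT3, and Src family) were not. A wrong grouping of the same 6 libraries called as many as 18 lists. It had R159 and vehicle libraries on both sides, and so kept part of the real contrast. Without R159 replicate 1 the fibrosis, lipid droplet, macrophage, cholangiocyte, CAR and PXR, ERK and stress response lists lost their calls, which left 12 of the 19. The B cell list lost its call without R159 replicate 2; the B cell, female-biased, lipid droplet and stress response lists without R159 replicate 3; the lipid droplet and macrophage lists without vehicle replicate 1; the CAR and PXR and stress response lists without vehicle replicate 2; and the ERK, female-biased and stress response lists without vehicle replicate 3.

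Among the largest single changes, Rsc1a1 was at 1226 ± 143 in R159 and 39.8 ± 29.7 in vehicle, but shares exon sequence with Ddi2. Ugt1a8, Trpc2 and Zfp708 likewise overlap other genes on the same strand, so their division of reads is uncertain; Ugt1a8 was at most 0.0509 estimated reads in every vehicle library and ranged from 20.2 to 1790.0 in R159. Lypd1, Tagln3, Zfp968 and Mss51 were low in vehicle and higher in R159, and Mup7 rose from 7170 ± 6288 to 84446 ± 65640. On the lower side, Tekt5 was listed at 0 in all 3 R159 libraries and at 43.3 ± 49.7 in vehicle. Pls1 fell from 281 ± 187 to 14.4 ± 14.5, and Cyp2a4, which has a near-identical neighbour, from 5226 ± 2683 to 588 ± 550. Zfp469, Mbnl3 and C2cd4c were also lower. Zbtb9, which overlaps Ggnbp1, and Pcdhgb4, which shares exons with the other genes of its protocadherin cluster, were called lower too, but their division of reads is uncertain.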

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

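The length correction, limma-voom and the coding-only fit were chosen after seeing the data. The planned edgeR and DESeq2 fits were not run, because whole reads could not be recovered. None of the 109 called named genes (0) and none of the 19 called lists (0) changed sign under the alternatives run. Of these genes, 51 were called under every alternative in which they were followed. That count leaves out the minimum log2 change of 1 and the threshold of 0.1. A gene that a setting dropped was not counted as lost there. Of the 118 named genes, 100 were tested at a minimum mean of 50, and 115 with coding genes only. Of the called lists, 7 were called under every alternative that kept the preset correlation, and 0 with an estimated correlation. In all 6 leave-one-out fits 68 of the genes and 10 of the lists were called. Leaving out 1 library cannot change the sign of a gene whose groups do not overlap, as held for 4442 of the 4479 called genes. Counts of called genes lay between 3085 (without the empirical Bayes trend, where genes lower dropped to 1443) and 6371 (adjusted p under 0.1), apart from the cases named next. A minimum log2 change of 1 left 2224 genes, 1338 higher and 886 lower. Removing the length trend left 2863 genes, 1293 of them lower; 2110 of them were also called, in the same direction, among the 4281 called genes with a length (49.3%), and 3 were called in the opposite direction. Leaving out 1 library gave 1854 to 5420 genes, 920 to 2516 higher and 934 to 2904 lower, and 13 to 20 lists. Without vehicle replicates 1, 2 and 3 the counts were 2498, 1854 and 2185 genes. Without R159 replicates 1, 2 and 3, where as many samples were fitted, they were 5420, 3348 and 3915. Lists called numbered 12 with coding genes only, 5 with fry, 0 with an estimated correlation (2 at an unadjusted p under 0.05), and 0 with an estimated correlation after removal of the length trend (0 at an unadjusted p under 0.05), the last chosen after seeing the data. Rescaling without the 20 highest genes put the median log2 fold change of all genes at -0.108, against 0.001 in the planned analysis. It called 3996 genes, 37.6% of them higher against 47.4%. The coding-only fit changed no values and only left genes out. Over its 13493 genes the median was -0.101, and 39.2% of its calls were higher. Among called genes without a coding record, the planned analysis had 678 higher and 108 lower. Apart from the changes of threshold and the genes left out of the coding-only fit, the causes of these shifts were not tested.

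The replicate block called 3945 genes (1912 higher, 2033 lower) and 19 lists. The values gave no clear sign that the shared numbers pair the samples, though 3 replicates per group cannot exclude it. Same-numbered deviations correlated at -0.098, 0.031 and 0.11, and only replicate 3 correlated best with its own number.

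Results that changed sign were all uncalled, and the cause was not tested. With quantile normalization the Kupffer list median was 0.045 and Tnf -0.129. Median centring gave the circadian list 0.002. A pseudocount of 8 gave the T and NK list 0.004; a minimum mean of 50 gave it 0.407 and the circadian list 0.006. Sample weights gave the lipogenesis list 0.073, circadian 0.042, immediate early 0.051, adipose 1.041, Socs3 -0.318 and Tnf -0.362. Rescaling without the 20 highest genes gave the bile acid list -0.007 and Socs3 -0.062. Length correction gave the sinusoidal endothelial list 0.018, circadian 0.157, pericentral 0.013 and immediate early 0.028. Across the leave-one-out fits the ranges were -0.166 to 0.166 (acute phase), -0.178 to 0.156 (Kupffer), -0.293 to 0.337 (T and NK), -0.347 to 0.143 (lipogenesis), -0.245 to 0.225 (immediate early), -0.461 to 0.834 (adipose), -0.211 to 0.010 (pericentral), -0.051 to 0.204 (bile acid), -0.221 to 0.059 (circadian), -0.126 to 0.288 (Socs3), -0.298 to 0.793 (Tnf) and -0.221 to 0.988 (Cyp7a1).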

Other observations

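Of 12 transcripts known to stay in the nucleus or to keep introns, limma called 8 higher in R159 and 4 not; they were chosen after their values were seen, so the count is no test of such transcripts as a group. Malat1, a nuclear long non-coding RNA, was at 9216 ± 2531 in R159 and 2518 ± 987 in vehicle (log2 fold change 1.91, SE 0.29, limma adjusted p = 0.00431). The splicing kinase genes Clk1 and Clk4 rose by 1.75 and 1.59 on the log2 scale, and Ccnl2 and Rsrp1 by 2.03 and 1.84 (limma adjusted p = 0.00299 to 0.00311 for these). Neat1 (0.92, adjusted p = 0.073), Ddx5 (0.59, adjusted p = 0.0747), Meg3 (1.54, adjusted p = 0.117) and Kcnq1ot1 (1.502, adjusted p = 0.0521) were not called.

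All tests of explanations below were chosen after the results were seen, except the splits of the samples. The real grouping called 4479 genes, and the highest of the other 9 splits of the 6 libraries called 0 with limma (119 to 668 genes at an unadjusted p under 0.05 across the 9, against 6880). For lists it called 19, and the highest of the others 18. Each other split had R159 and vehicle libraries on both sides, so it kept part of the real contrast. The rest of the group difference went into the spread between libraries, which lowers the calls of single genes. The other splits are therefore not free of treatment, and their counts cannot tell treatment from other structure. The real grouping was the only 1 of the 10 splits to call as many genes, and the only 1 to call as many lists, but 10 splits are too few for a share under 0.05.

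Short transcripts were higher and long ones lower in R159. A difference in depth is argued against, since among coding genes with a mean of at least 1000 the correlation with length was stronger (rho = -0.572). A single library is argued against too, since rho was -0.418 without R159 replicate 2. A bias in RNA integrity or library preparation remains open. For deviations from the mean of all libraries, rho differed by 0.618 among the 3 R159 libraries, which received the same treatment. Measured against the vehicle mean, rho was -0.241, -0.578 and -0.524 in R159 replicates 1, 2 and 3. By that measure rho was negative in each R159 library, and the values lay closer together. The rises of ribosomal protein (median 0.959) and respiratory chain genes (0.776, over members with a known length) lie inside the range of lists matched on length and expression. They may be part of this trend. The matched lists left out only a list's own members, so other ribosomal and respiratory chain genes could be drawn. The range therefore cannot tell a length trend from a rise of these gene classes. An effect of R159 on transcript classes stays open as well, as untested.

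The medians of the interferon, NRF2, fibrosis and lipid droplet lists, -0.972, -0.75, -0.722 and -0.539, lie below the central 95% of matched random lists. Removing the length trend left medians of -1.003, -0.798, -0.494 and -0.728. Lists that camera did not call also lay outside their ranges, such as cytokines (-0.413, below -0.084) and bile acid (0.103, above 0.095). Random lists draw unrelated genes, so the range is narrow for genes that move together. Lying outside it does not single out these falls. For the fibrosis list, a lower share of several non-hepatocyte cell types stays open. Its length-corrected median differed from that of the markers of 7 other non-hepatocyte lists by -0.272 (bootstrap interval over genes -0.587 to 0.00852). Macrophage (-0.965) and cholangiocyte markers (-0.887) had lower medians than the fibrosis list (-0.494, interval -0.713 to -0.428). Endothelial (0.0184, interval -0.204 to 0.279) and B cell markers (0.485, interval 0.15 to 0.743) had medians above 0. The intervals of these last lists lie above that of the fibrosis list. As far as intervals over genes go, this argues against an equal fall of all these cell types. Genes of a list are not independent, and a change in stellate cells alone was not tested. Other groupings of the libraries, each with R159 and vehicle libraries on both sides, called nearly as many lists. A treatment effect is therefore a hypothesis only.

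Erythroid transcripts were higher than lists matched on length and expression (median 2.199, above 1.153), and removing the length trend left a median of 1.291. Random lists draw unrelated genes, so this argues only weakly against transcript length as the whole cause. More blood left in the tissue could bring erythroid transcripts, and would also bring granulocyte transcripts. S100a8 and S100a9, neither of them called (limma adjusted p = 0.11 and 0.119), gave a mean log2 fold change of 1.32 (SE 0.405) before and 0.0827 (SE 0.372) after length correction, and of 12 neutrophil markers 8 had a log2 fold change above 0 and 4 (Mmp9, Ngp, Ltf and Lcn2) below (1 called higher; camera adjusted p = 0.296). The granulocyte check thus moves with the length trend, and whether blood is the source of the erythroid rise stays open. Hba-a1 and Hba-a2 are near-identical copies, and their values are uncertain singly.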
